A study of Mus musculus with 6 samples.

How the data were processed

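RNA was measured in mammary tumours of Balb/c mice. The tumours grew from 4T1 cells, a mouse mammary carcinoma line that is syngeneic to this strain. Per the labels, 500000 cells were placed in the inguinal mammary fat pad of mice that were 10 weeks old, and after tumours had formed the mice received either DMSO, the vehicle, or Vismodegib at 2 mg per mouse, 3 times per week for 3 weeks. Vismodegib is a small molecule that binds Smoothened, the membrane protein through which Hedgehog ligands signal. Whole tumours were frozen, RNA was taken up in Trizol, and a sequencing service prepared Illumina libraries that were read as pairs of 150 bases. There were 3 DMSO and 3 Vismodegib libraries, grouped by their titles. The labels call them samples of treated tumours and do not state that each came from its own animal, so the p-values measure the spread between these samples.

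The authors deposited a table of RPKM values (reads per kilobase of gene, scaled to the library's total reads) for 23381 gene symbols in the 6 libraries. Per the submitters' processing notes, bcl2fastq 2.17, cutadapt, STAR, HISAT2, SAMtools and Partek were used with the mm10 build; the role and order of these tools, the annotation and the use of strand are not given in the sources used here. The values contain fractions of reads, as estimation software that shares reads between transcripts gives, so that near-identical copies, overlapping genes and antisense genes are uncertain. RPKM divides by the library total, so a gene's value also depends on how much RNA the other genes contributed.

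The depth behind the values was recovered from their steps. The steps came from 6992 genes with 1 transcript in the GENCODE M21 annotation of the same build. Taken as 1 read, each step implies a total through the transcript length. Of the steps at least 0.5 times as common as the most common step, the step with the highest total was used. This gave totals of 37500000, 34800000 and 40500000 reads for DMSO replicates 1, 2 and 3, and 41600000, 42700000 and 58000000 for Vismodegib replicates 1, 2 and 3. With these totals, between 83.6% and 85.2% of the low values, up to 20 reads, were whole numbers of reads within 0.02 reads. This check cannot detect a total that is too high by a whole-number factor, since whole counts would stay whole. Whether a read or a read pair was counted is not stated. A transcript of 2 kb at 0.5 RPKM rests on 34.8 to 58.0 reads per library. None of 16 housekeeping genes was listed at 0 in any library, and 4052 to 5313 genes per library were. Limits set from 3 reads cover counting error only.

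The choices in this paragraph were made before the data were examined. Genes with a mean of at least 0.5 RPKM over the 6 libraries were tested, 11818 in all, on log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with group as the only term, two-sided, and Benjamini-Hochberg adjustment over all genes tested. Differences are Vismodegib minus DMSO on this scale, which understates the change of low genes. Of 49 gene lists, 46 had at least 5 tested members and were compared with the other genes by limma's camera with a preset correlation of 0.01 between genes. The lists cover the Hedgehog pathway, immune, stromal, epithelial and other cell types a dissected fat pad tumour can hold, metabolism, cell cycle, stress and signalling. Of 983 list members, 958 were matched to a row, 14 of them through another symbol in the RefSeq gene table. The rule for named genes took every measured Hedgehog list member, with Gli1, Ptch1 and Hhip among those in full; 1 measured member, too low to be tested, is not reported here. It also took the 10 highest and 10 lowest genes past the threshold with a mean of at least 1 RPKM, filled up with the smallest unadjusted p where fewer passed, and up to 4 members with the smallest unadjusted p of each list whose members are described. Shh and Scube2, also on the Hedgehog list, were not analysed here. One choice came later: the 6 lists that did not pass and whose members are described nonetheless, 5 immune lists and the unfolded protein response, were chosen after the data were seen.

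Alternatives changed 1 choice at a time. They covered the pseudocount, the filter, median-ratio and quantile scaling, eBayes without a trend or with robust estimation, library weights, the replicate number as a block, each library left out, camera with an estimated correlation or on ranks, and fry. Removal of each library's trend on GC content and length, and leaving out 2 libraries together, were added after the data were seen. Length and GC content came from the longest GENCODE M21 transcript and were found for 11613 of the genes tested.

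The steps were tested on simulated data. Values for the 11818 genes were drawn in 20 rounds from the gene means and fitted variances of the 6 libraries, each gene independently. In each round, 200 genes were given folds of 2, 4 or 8 between Vismodegib and DMSO. The limma step recovered 12.2% of genes with a fold of 2, 91.1% with a fold of 4 and 99.1% with a fold of 8, and 6.33% of its calls were wrong. For lists of independent genes, camera called 89 of 100 lists moved by 0.5 on the log2 scale. It called on average 0.05 lists per round, of 46, where no gene had been moved. Recovery of moved lists was not simulated for genes that vary together, nor for an estimated correlation or fry. Where the genes of a list varied together at the correlation estimated for it, 12.7 unchanged lists per round were called on average, between 5 and 19, and none with an estimated correlation. Tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Positions are GENCODE M21 gene bounds on mm10, counted from 1.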

Results

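The data comprised RPKM values of 23381 genes in 3 vehicle-treated and 3 Vismodegib-treated 4T1 mammary tumours, at 34800000 to 58000000 reads per library. The single comparison asked what blocking Smoothened, and with it Hedgehog signalling, did to the RNA of the whole tumour. In the treated tumours, lists of fat, skeletal muscle, fibroblast, matrix, epithelial and mitochondrially encoded genes stood higher than other genes, with list medians of 0.46 to 1.26 on the log2 scale. Interferon-stimulated, mitotic and ribosomal protein genes stood slightly lower, with medians of -0.19, -0.17 and -0.06. These 9 list differences passed camera with a preset correlation and none passed with an estimated correlation, where the smallest adjusted p = 0.688. Other splits of the libraries into groups of 3 gave 9 to 16 lists with the preset correlation. Of the 9 lists, only the epithelial list had per-library medians that did not overlap between the groups. The Hedgehog pathway list did not pass (adjusted p = 0.84), and no single gene passed limma's test at an adjusted p under 0.05.

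Of the transcripts that report Hedgehog pathway activity, Gli1 lay near the floor of detection and Ptch1 was low in both groups, while Hhip passed the filter of 0.5 RPKM. Gli1, the transcription factor that is both a mediator and a target of the pathway (ENSMUSG00000025407.7, chromosome 10, 127329882 to 127341974, minus strand), was at 0.080, 0 and 0.020 RPKM in DMSO replicates 1, 2 and 3 and at 0.024, 0 and 0 RPKM in Vismodegib replicates 1, 2 and 3. For the length of 4057 bases used here, 3 reads correspond to 0.0128 to 0.0212 RPKM, which leaves little room for a fall in Gli1 to be detected at this depth. Ptch1, which encodes the Hedgehog receptor and is induced by the pathway (ENSMUSG00000021466.12, chromosome 13, 63508328 to 63573598, minus strand), was at 0.244 ± 0.145 RPKM in DMSO and 0.214 ± 0.087 RPKM in Vismodegib (mean ± SD, n = 3 libraries per group). Hhip, a secreted antagonist and pathway target (ENSMUSG00000064325.4, chromosome 8, 79965851 to 80058006, minus strand), was at 1.09 ± 1.20 RPKM in DMSO and 1.05 ± 0.198 RPKM in Vismodegib, the DMSO spread coming from 2.46 RPKM in replicate 1 against 0.237 and 0.569 RPKM in replicates 2 and 3. Two-sided exact permutation tests of the log2 values gave p = 0.7 for Gli1, p = 0.8 for Ptch1 and p = 0.8 for Hhip, where 0.1 is the smallest p that 3 against 3 allows.

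Of the 19 members of the Hedgehog list reported here, 11 were expressed high enough to be tested. Of these 11, 5 had differences above 0 and 6 below, none passed over all genes, and 0 passed when adjusted over the list alone. The largest difference was in Gas1, which encodes a cell surface co-receptor for Hedgehog ligands. Gas1 was at 1.39 ± 0.154 RPKM in DMSO and 2.97 ± 0.818 RPKM in Vismodegib, with all 3 treated tumours above all 3 controls. Its log2 difference was 0.85 (SE 0.269), with adjusted p = 1 over all genes and 0.133 over the list by limma. Smo, the drug's target, was at 3.54 ± 0.450 RPKM in DMSO and 4.38 ± 0.346 RPKM in Vismodegib. Its log2 difference of 0.27 had a 95% interval from -0.27 to 0.82. Differences of -0.05 for Gli3, -0.07 for Sufu, 0.21 for Boc, -0.51 for Cdon, -0.04 for Gpr161, -0.09 for Evc, -0.17 for Evc2 and 0.35 for Hhipl1 also did not pass. Gli2, Ihh, Dhh, Disp1, Hhat and Kif7 had group means between 0.018 and 0.482 RPKM and were too low to be tested by limma. Among these, Dhh, which encodes a Hedgehog ligand, was at 0.310, 0.106 and 0.174 RPKM in DMSO and at 0.449, 0.401 and 0.361 RPKM in Vismodegib, without overlap (exact permutation p = 0.1), and the others had exact permutation p between 0.4 and 1. The groups also did not overlap in Smo and Hhipl1. The list's median was -0.04, its mean was 0.09, and camera put it slightly above other genes (adjusted p = 0.84). The sign of the median followed single libraries. It was 0.09 without DMSO replicate 1, 0.02 without DMSO replicate 3, 0.002 without Vismodegib replicate 1 and 0.08 without Vismodegib replicate 3, and 0.03 with no filter on low values.

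**Figure D1:**
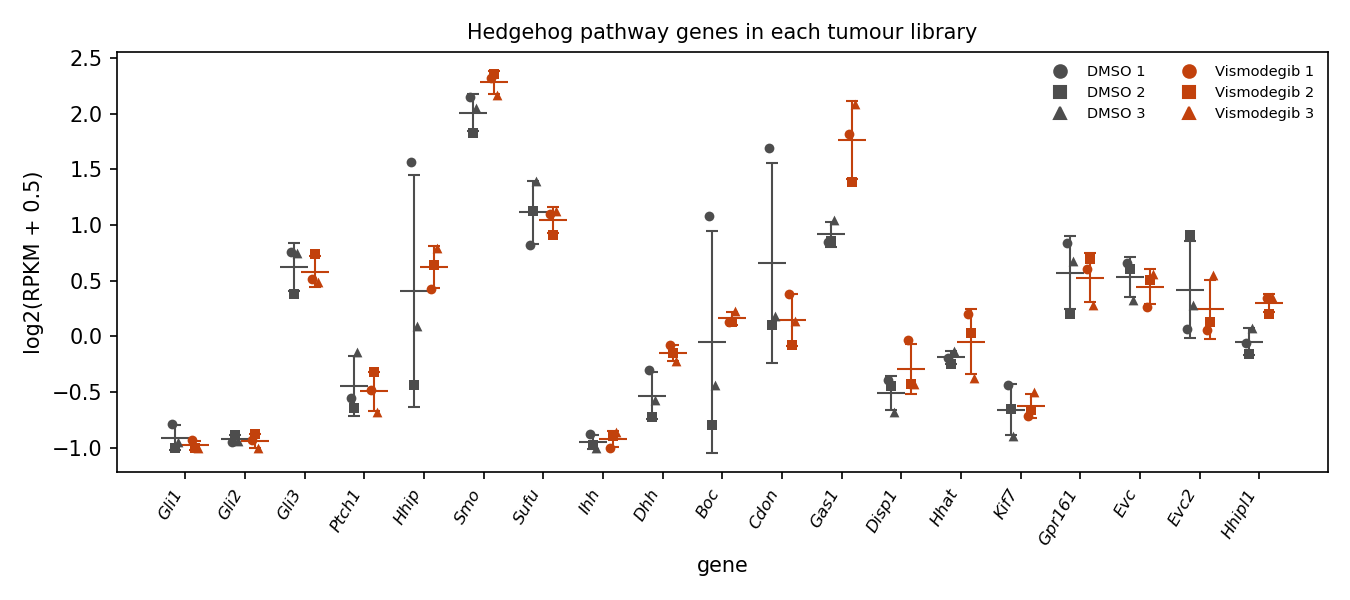
Expression of 19 Hedgehog list members, as log2(RPKM + 0.5) on the vertical axis, in 3 DMSO libraries (grey) and 3 Vismodegib libraries (orange). Symbols are single libraries, horizontal ticks are group means and bars are 1 SD. Gli1, Gli2 and Ihh lie at the bottom of the range in every library, and Gas1 is the member with the largest difference, 0.85.

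Across the whole transcriptome, no gene of 11818 passed limma's test, whose smallest adjusted p = 1. At an unadjusted p under 0.05 there were 266 genes, 229 higher and 37 lower in Vismodegib, where chance alone would give 590.9. In 595 genes, or 5.03%, the groups did not overlap, against 10% by chance. The gene with the smallest p was Apoc1, an apolipoprotein of triglyceride-rich lipoproteins that macrophages also make, at 1.25 ± 0.754 RPKM in DMSO and 7.12 ± 0.821 RPKM in Vismodegib (n = 3 each). Its log2 difference was 2.22, with a 95% interval from 1.42 to 3.01. The other leading genes in this direction included Krt15, a keratin of basal epithelial cells (2.21 ± 0.685 RPKM against 6.76 ± 0.784 RPKM), and Tmprss4, an epithelial transmembrane protease (2.19 ± 0.979 RPKM against 6.63 ± 0.885 RPKM). Il18r1, the receptor subunit that binds interleukin 18, was at 1.03 ± 0.053 RPKM in DMSO and 3.16 ± 0.819 RPKM in Vismodegib, and Rgs1, a regulator of G protein signalling in lymphocytes, was at 0.410 ± 0.194 RPKM and 1.67 ± 0.255 RPKM. Itm2a, Fam25c, 2610528J11Rik, G430095P16Rik and Gm49540 completed the 10 genes, with log2 differences of 1.76, 2.57, 1.27, 1.29 and 2.32. Gm49540 lies antisense within the muscle gene Mb and G430095P16Rik overlaps Nfix on the other strand, so that their reads cannot be assigned with certainty.

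In the other direction, the smallest p belonged to Ccl24, an eosinophil-attracting chemokine made by alternatively activated macrophages. Ccl24 was at 24.8 ± 7.63 RPKM in DMSO and 9.09 ± 3.10 RPKM in Vismodegib, with a log2 difference of -1.40 and a 95% interval from -2.16 to -0.64. Socs1, a feedback inhibitor of cytokine signalling, was at 28.7 ± 10.8 RPKM against 13.01 ± 4.58 RPKM. The lytic granule genes Prf1 and Gzmg had log2 differences of -0.69 and -2.97; Gzmg was at 28.2 RPKM in DMSO replicate 2 and at most 5.63 RPKM elsewhere. Grp, which encodes gastrin-releasing peptide, was at 19.4 RPKM in DMSO replicate 3, at 3.67 RPKM in replicate 2 and at no more than 0.090 RPKM in the other 4 libraries. Adamdec1, Rad9a, Gm16845 and the histone genes H2ac20 and H2ac7 had differences between -0.74 and -1.06; the histone genes and Gzmg have close relatives that can share reads, and Gm16845 overlaps Ecsit on the other strand. Of these 20 genes, 16 had groups that did not overlap, and none passed adjustment. Without DMSO replicate 1, 19 genes passed, 11 higher and 8 lower, among them Apoc1, Grp and Gzmg. Library weights that limma estimated at 7.28 for DMSO replicate 3 and 0.32 for each of the other DMSO libraries gave 420 genes, 306 higher and 114 lower. In simulated data of this size, 91.1% of genes with a fold of 4 and 12.2% of genes with a fold of 2 were recovered. The simulated genes varied independently and 200 were changed per round. These shares may not hold here, where genes vary together and Apoc1, with a log2 difference of 2.22, did not pass.

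**Figure D2:**
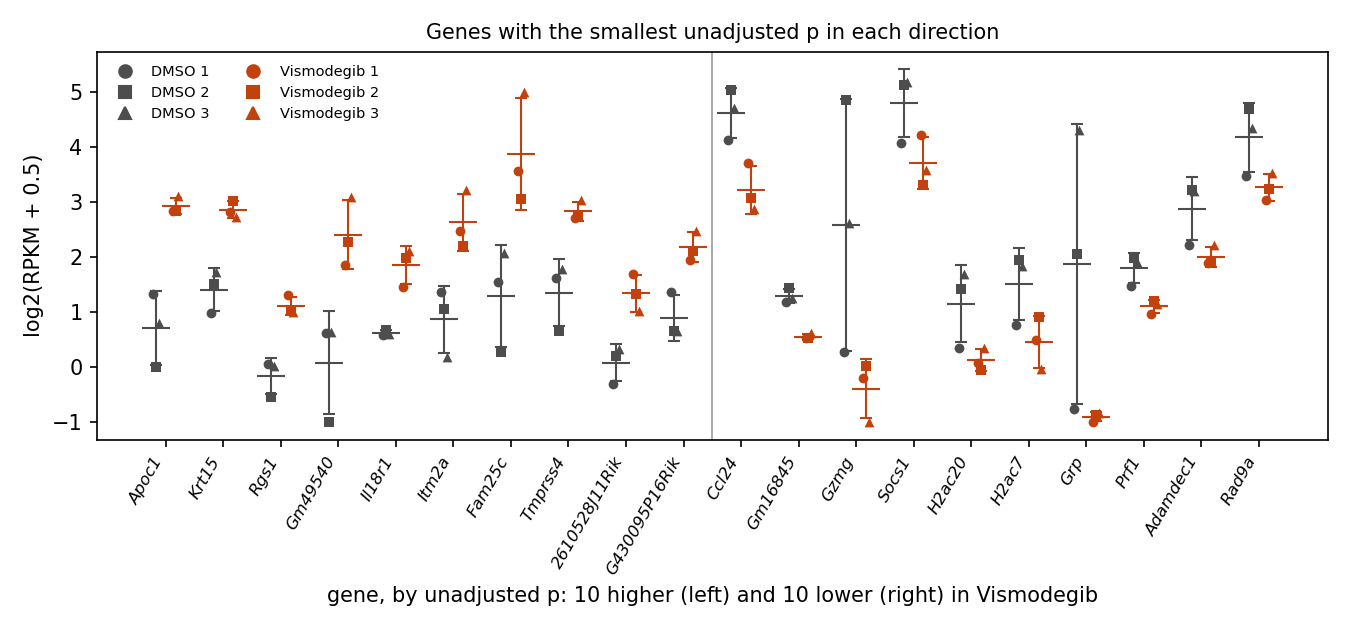
Expression of the 10 genes with the smallest unadjusted p in each direction, as log2(RPKM + 0.5) on the vertical axis, with the 10 higher in Vismodegib to the left of the line and the 10 lower to the right. Symbols are single libraries of DMSO (grey) and Vismodegib (orange), horizontal ticks are group means and bars are 1 SD. The groups do not overlap in 16 of the 20 genes, and none passed adjustment.

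Genes of fat and muscle had the largest list differences. The adipocyte list had 11 tested members, all with values above 0 and a median of 1.26, which passed camera (adjusted p = 2.06e-06) but not with the correlation estimated from the data (adjusted p = 0.688 with an estimated correlation). Lpl, the lipase that releases fatty acids from lipoproteins, was at 0.264 ± 0.162 RPKM in DMSO and 1.496 ± 0.922 RPKM in Vismodegib. Scd1, a fatty acid desaturase, was at 16.6 and 18.9 RPKM in Vismodegib replicates 1 and 2, but at 2.34 RPKM in replicate 3, within the 1.78 to 3.12 RPKM of the DMSO tumours. The lipid droplet gene Cidec and the adipokine gene Retn followed the same libraries, with 2.73, 3.20 and 0.26 RPKM and with 3.03, 5.93 and 0.03 RPKM in Vismodegib replicates 1, 2 and 3. The list's median was 2.07 without Vismodegib replicate 3, 0.38 with no filter on low values and 0.64 over members with a mean of at least 2 RPKM. All 15 tested skeletal muscle genes had values above 0, with a median of 1.15 (camera, adjusted p = 3.6e-07, and adjusted p = 0.715 with an estimated correlation). Tnnt3, fast muscle troponin T, was at 11.9 ± 7.38 RPKM in DMSO and 31.3 ± 6.68 RPKM in Vismodegib. Ckm, muscle creatine kinase, was at 4.34, 26.1 and 0.26 RPKM in DMSO replicates 1, 2 and 3 against 39.1, 17.9 and 14.9 RPKM in Vismodegib, and Pvalb and Tpm2 had log2 differences of 2.14 and 0.75. The muscle median was 2.14 with library weights, 2.15 without DMSO replicate 2, 0.58 without DMSO replicate 3 and 0.76 without Vismodegib replicate 1. None of the adipocyte or muscle genes passed over all genes, and none did when adjusted over the list alone.

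Connective tissue genes stood higher by smaller amounts. In the fibroblast and pericyte list, 18 of 19 tested members had values above 0, with a median of 0.52 (camera, adjusted p = 4.39e-06, and adjusted p = 0.688 with an estimated correlation). Lum, a collagen-binding proteoglycan, was at 1.86 ± 0.475 RPKM in DMSO and 5.63 ± 2.13 RPKM in Vismodegib. The collagen genes Col3a1 and Col1a2 were at 8.34 ± 4.31 and 14.2 ± 1.86 RPKM in DMSO and at 19.96 ± 6.96 and 31.1 ± 13.2 RPKM in Vismodegib, and Postn had a log2 difference of 0.85. The median was 0.84 without Vismodegib replicate 2 and 0.29 without Vismodegib replicate 3. In the extracellular matrix list, 26 of 29 tested members had values above 0, with a median of 0.46 (camera, adjusted p = 2.86e-07, and adjusted p = 0.688 with an estimated correlation). Tnc, the matrix glycoprotein tenascin C, was at 12.2 ± 4.57 RPKM in DMSO and 22.8 ± 5.23 RPKM in Vismodegib, and Thbs2, Col8a1 and Thbs1 had log2 differences of 0.81, 0.68 and 1.21. For both lists, 0 members passed over all genes and 0 when adjusted over the list alone.

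Epithelial genes and transcripts of the mitochondrial genome were also higher. In the epithelial and keratin list, 22 of 24 tested members had values above 0, with a median of 0.53 (camera, adjusted p = 2.86e-07, and adjusted p = 0.688 with an estimated correlation). Elf3, an epithelial transcription factor, was at 20.02 ± 13.3 RPKM in DMSO and 56.6 ± 14.9 RPKM in Vismodegib. The tight junction gene Cldn4 was at 248 ± 78.8 and 452 ± 70.8 RPKM, Krt7 at 56.0 ± 12.9 and 95.2 ± 7.59 RPKM, and Epcam, a surface adhesion molecule of epithelial cells, at 208 ± 72.5 and 390 ± 121 RPKM. The per-library medians of this list, unlike those of the other 8 that passed, did not overlap between the groups. The gap was narrow, from 0.165 in DMSO replicate 3 to 0.221 in Vismodegib replicate 2, and by chance 10% of lists would not overlap. Library weights lowered its median to 0.25 and ended the call (adjusted p = 0.215). All 13 mitochondrially encoded genes had values above 0, with a median of 0.91 (camera, adjusted p = 2.86e-07, and adjusted p = 0.688 with an estimated correlation). mt-Nd3, a subunit of respiratory complex I, was at 396 ± 205 RPKM in DMSO and 916 ± 282 RPKM in Vismodegib, and mt-Co2, mt-Cytb and mt-Nd1 had log2 differences of 0.76, 0.66 and 0.68. All transcripts of the mitochondrial genome, ribosomal RNA included, made up 3.89%, 1.10% and 1.90% of the RPKM sum in DMSO replicates 1, 2 and 3, and 4.14%, 3.68% and 2.62% in Vismodegib. The median was 0.44 without DMSO replicate 2 and 0.58 without Vismodegib replicate 1. Beside these shares, GC-rich genes were relatively low in Vismodegib replicates 1 and 2 and high in Vismodegib replicate 3 and DMSO replicate 2. The correlations across genes between GC content and the deviation from the gene's mean were -0.22, -0.35, 0.29 and 0.21 in these libraries. They were -0.15 in DMSO replicate 3 and -0.04 in DMSO replicate 1. With the log of transcript length, they ran from -0.2 in DMSO replicate 2 to 0.27 in DMSO replicate 3. With each library's trend on GC content and length removed, the mitochondrial median was 0.52. No member of either list passed over all genes, and 0 passed when adjusted over the list alone.

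The lists that stood lower had medians closer to 0. In the interferon-stimulated list, 29 of 35 tested members had values below 0, with a median of -0.19 (camera, adjusted p = 1.78e-05, and adjusted p = 0.855 with an estimated correlation). Isg15, a ubiquitin-like protein induced by interferon, was at 301 ± 80.8 RPKM in DMSO and 218 ± 12.4 RPKM in Vismodegib, and Gbp3, Ifit3b and Stat2 had log2 differences of -0.56, -0.82 and -0.43. Without DMSO replicate 3 the median was -0.01 and the list did not pass (adjusted p = 0.0856), and it was -0.42 without DMSO replicate 1 and -0.495 with library weights. In the G2/M list, 26 of 30 members had values below 0, with a median of -0.17 (camera, adjusted p = 9.29e-04, and adjusted p = 0.976 with an estimated correlation). Top2a, the topoisomerase of dividing cells, was at 9.91, 37.1 and 22.6 RPKM in DMSO and at 16.2, 16.7 and 14.6 RPKM in Vismodegib, so that the treated tumours lay between the lowest and the highest control. Foxm1, Mki67 and Hmmr had differences of -0.38, -0.28 and -0.34. Without DMSO replicate 2 the median turned to 0.12 (adjusted p = 0.573), and without DMSO replicate 1 it was -0.54. Of 38 ribosomal protein genes, 28 had values below 0, with a median of -0.06 (camera, adjusted p = 0.0495, and adjusted p = 0.976 with an estimated correlation). Rps6, Rps20 and Rps2 had differences of -0.39, -0.41 and -0.39 and Rps24 of 0.26. The ribosomal median turned to 0.19 without DMSO replicate 2, and the call ended without Vismodegib replicate 1 (-0.06, adjusted p = 0.444), without Vismodegib replicate 3 (-0.001, adjusted p = 0.136), with a pseudocount of 1 (-0.059, adjusted p = 0.0557), with no filter (-0.06, adjusted p = 0.203) and with quantile scaling (-0.11, adjusted p = 0.0692). With library weights it turned to 0.091 (adjusted p = 0.396). It was -0.23 without DMSO replicate 1, -0.16 without DMSO replicate 3, -0.14 without Vismodegib replicate 2, -0.13 with median-ratio scaling and -0.153 with trends on GC content and length removed. For these 3 lists too, 0 members passed over all genes and 0 when adjusted over the list alone.

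**Figure D3:**
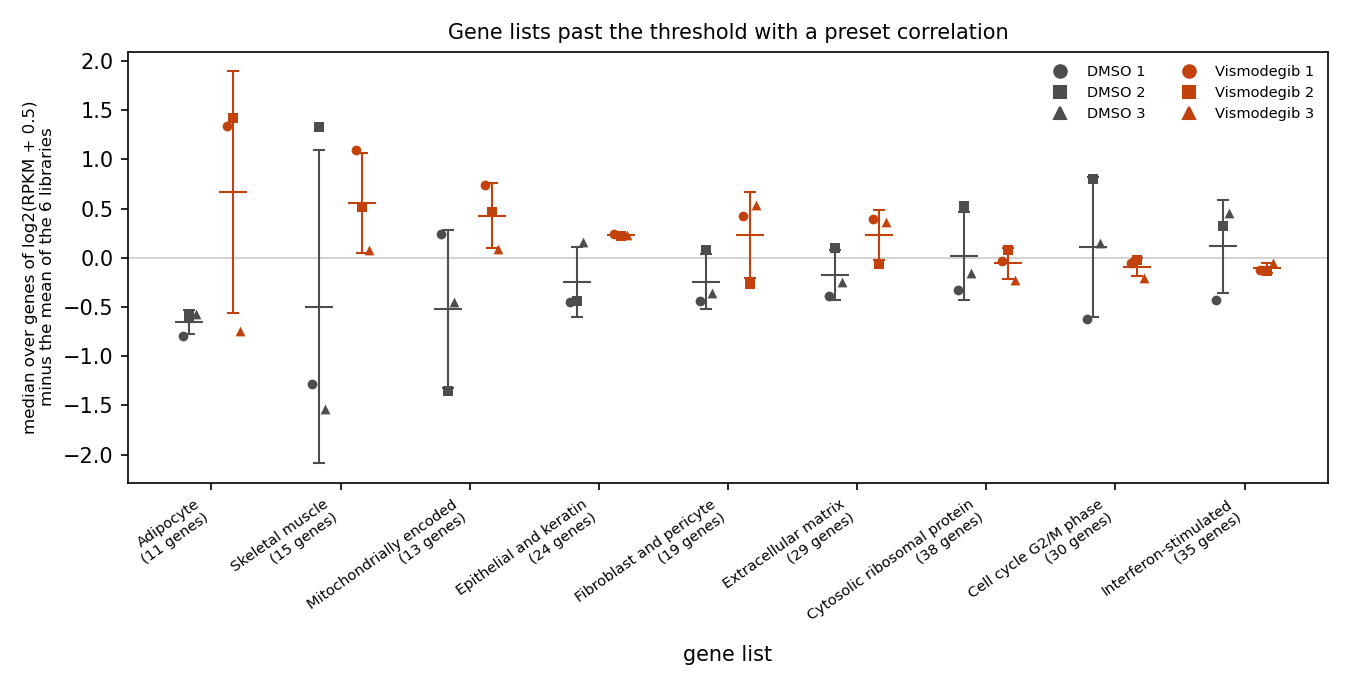
Gene lists past the threshold with a preset correlation. The vertical axis is the median over a list's tested genes of log2(RPKM + 0.5) minus the gene's mean over the 6 libraries, for DMSO (grey) and Vismodegib (orange); symbols are single libraries, ticks are group means and bars are 1 SD. The adipocyte values of Vismodegib replicates 1 and 2 are 1.34 and 1.42 and that of replicate 3 is -0.75, and the muscle value of DMSO replicate 2, 1.33, is above all Vismodegib libraries; G2/M and ribosomal medians change sign without DMSO replicate 2.

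Immune genes were among the cell type lists fixed beforehand. The immune lists described here did not pass, and they were chosen for description after the data were seen. The macrophage marker list had 18 tested members with a median of -0.15 and did not pass (camera, adjusted p = 0.187). C1qb, a complement subunit abundant in tissue macrophages, was at 182 ± 25.5 RPKM in DMSO and 154 ± 54.8 RPKM in Vismodegib. Cd68 and Trem2 had log2 differences of -0.49 and -0.29, while Cd14, the co-receptor for lipopolysaccharide, was at 11.7 ± 2.10 RPKM in DMSO and 24.2 ± 11.1 RPKM in Vismodegib. Among 16 tested genes linked to alternative activation, the median was -0.10 (adjusted p = 0.259). Here 0 genes passed over all genes and 1, Ccl24, passed adjusted over the list alone (0.0412), while Il10, Socs2 and Stat6 had differences of 0.56, 0.64 and -0.29. Among 17 genes induced by lipopolysaccharide or interferon gamma, the median was -0.14 (adjusted p = 0.504); Ccr7, Cd86 and Il1b had differences of 0.48, 0.46 and 0.64, and Irf1 was at 87.5 ± 10.9 RPKM in DMSO and 68.9 ± 2.11 RPKM in Vismodegib. The cytotoxic lymphocyte list had 13 tested members with a median of -0.09 (adjusted p = 0.0543). Its members Prf1, which encodes perforin, and Ccl5 were at 3.00 ± 0.626 and 29.3 ± 3.18 RPKM in DMSO and at 1.65 ± 0.182 and 21.1 ± 4.04 RPKM in Vismodegib, while Xcl1 and Klrd1 had differences of 0.48 and 0.41. The regulatory T cell and checkpoint list had 11 tested members with a median of -0.15 (adjusted p = 0.0543). Pdcd1lg2, which encodes a ligand of the PD-1 receptor, was at 3.61 ± 1.27 RPKM in DMSO and 1.77 ± 0.685 RPKM in Vismodegib. Tigit, an inhibitory receptor, ranged from 0.73 to 24.3 RPKM in DMSO and from 0.49 to 3.56 RPKM in Vismodegib, and Havcr2 had a difference of -0.42.

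These list calls rest on treating the genes of a list as nearly independent. The median of the correlations estimated within the 46 lists was 0.312, and with such correlations camera at its preset value called 5 to 19 unchanged lists per round in simulated data, against 9 here. With fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 0 lists passed.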

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

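The count of genes past the threshold was 0 in every alternative but 3. Library weights gave 420 genes (306 higher, 114 lower; the weight estimation stopped before converging), and between 0 and 19 genes passed, 0 to 11 higher and 0 to 8 lower, when each library was left out in turn, the highest count without DMSO replicate 1. With weights estimated anew for each, the other splits of the 6 libraries gave at most 50 genes. The replicate block gave 1 gene, Fam25c (1 higher, log2 difference 2.57, adjusted p = 0.0418). Same-numbered libraries deviated from their group means with correlations of 0.003, 0.038 and -0.305. Unlike-numbered libraries of different groups had correlations from -0.231 to 0.303. The values give no sign of pairing by number, but so few pairs cannot exclude it, and the labels do not state it.

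The 9 lists became 15 with a mean of at least 2 RPKM, 17 with library weights, 0 with an estimated correlation and 0 with fry, and 10 to 16 when each library was left out; the cause was not tested except that an estimated correlation widens each list's error. With ranks, 9 of the 9 kept their call and direction, with GC content and length trends removed (added after the data were seen) also 9, and with a library left out 7 to 9. Leaving out both DMSO replicate 2 and Vismodegib replicate 3 (also added) gave 0 genes and 13 lists, 7 of them among the 9. Scaling moved the median of all genes from 0.06 to -0.01 (median ratio) or -0.02 (quantile).

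The Hedgehog median of -0.04 turned to 0.034 without a filter and 0.083 with library weights; it was -0.095 and -0.145 with median-ratio and quantile scaling, -0.070 with GC content and length trends removed and -0.107 with both libraries left out, and ranged from -0.063 to 0.089 with single libraries left out; camera's adjusted p ran from 0.157 to 0.984 over the alternatives in which the list was tested. G2/M turned to 0.19 and ribosomal protein genes to 0.29 with both libraries left out, the latter also to 0.091 with library weights, and adipocyte, muscle and mitochondrial genes moved to 2.12, 2.39 and 0.56 with both left out; with 1 library left out the G2/M and ribosomal medians ranged from -0.54 to 0.12 and from -0.23 to 0.19.

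Of 88 named genes, all kept their direction under the pseudocounts, filters (65 genes with a mean of at least 2 RPKM), scalings, eBayes settings and the block; 82 to 87 did with a library left out, 87 with library weights and 79 with both libraries left out. Ranges with 1 library left out that cross 0 were -0.17 to 0.019 for Gli3, -0.21 to 0.80 for Hhip, -0.22 to 0.068 for Sufu, -0.16 to 0.78 for Boc, -0.79 to 0.003 for Cdon, -0.23 to 0.089 for Gpr161, -0.19 to 0.002 for Evc, -0.35 to 0.069 for Evc2, -0.50 to 0.035 for C1qb, -0.73 to 0.019 for Hmmr, -0.85 to 0.073 for Top2a and -0.95 to 0.092 for Rps20. With both libraries left out, the values were -0.29 for Hhip, -0.19 for Boc, 0.10 for Cd68, 0.056 for Foxm1, 0.31 for Hmmr, 0.13 for Top2a, 0.11 for Rps6, 0.12 for Rps20 and 0.16 for Rps2, and library weights gave 0.083 for Evc. The cause of these turns was not tested beyond the libraries named. Depth limits Gli1, Gli2 and Ihh, whose values correspond to about 12.6 reads or fewer per library.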

Other observations

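The remaining fixed lists did not pass camera (adjusted p between 0.0543 and 0.949 over the 37 that did not pass), and their medians are given as values. Among other cell types, the medians were 0.41 for nerve and Schwann cell genes, 0.34 for endothelial genes, 0.12 for mast cells, 0.05 for erythroid genes, 0.03 for dendritic cells, -0.06 for T cells, -0.09 for neutrophils and -0.32 for B and plasma cells. In metabolism they were 0.16 for hexosamine and O-GlcNAc genes, 0.15 for fatty acid oxidation, 0.12 for fatty acid synthesis, 0.08 for nuclear oxidative phosphorylation genes, 0.02 for the tricarboxylic acid cycle, -0.11 for cholesterol synthesis and -0.24 for glycolysis. For signalling and stress they were 0.15 for Wnt targets, 0.11 for Notch, 0.10 for chemokines, 0.10 for immediate early genes, 0.07 for epithelial-mesenchymal transition, 0.06 for p53 targets, 0.05 for heat shock, -0.01 for hypoxia, -0.10 for drug metabolism and -0.17 for angiogenesis. They were 0.04 and -0.05 for MHC class I and class II presentation, -0.02 for S phase, -0.36 for replication-dependent histones and 0.02 for housekeeping genes. In the unfolded protein response list (24 genes, median 0.12, mean -0.08, adjusted p = 0.448), no member passed over all genes or over the list alone. Asns, asparagine synthetase, was at 14.4 ± 8.18 RPKM in DMSO and 5.82 ± 0.617 RPKM in Vismodegib, Chac1 and Sesn2 had log2 differences of -1.50 and -0.83, and Atf4, a transcription factor, of -0.49. In each of these genes DMSO replicate 1 lay within the range of the Vismodegib libraries, for Asns at 6.27 RPKM against 5.14 to 6.34 RPKM. Of the list's 24 members, 14 had values above 0 and 10 below. In 12 of the 37 lists the median, the mean and camera's direction differed in sign, among them Hedgehog, unfolded protein response, T cell, neutrophil and heat shock genes. Lymph node stroma, normal mammary and nuclear noncoding RNA lists had 3, 4 and 3 tested members and were not tested (medians 0.56, 0.93 and -0.58); in the mammary list, Krt15 alone passed adjusted over the list alone (0.00253).

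Immunoglobulin transcripts, singled out after their values were seen, varied widely between tumours of the same group. Igkc was at 4.92, 640 and 1762 RPKM in DMSO replicates 1, 2 and 3 and at 857, 116 and 19.9 RPKM in Vismodegib, and Ighg1 at 0.12, 12.9 and 294 RPKM and at 81.5, 7.23 and 1.98 RPKM. Vismodegib replicate 3 had the highest total, 58000000 reads, yet the most genes at 0 (5313 against 4052 to 5134). It also had the fewest genes at the most common step of its values (194 against 384 to 561). The sum of 25 small intestine genes, weighed below, was 59.51 RPKM in DMSO replicate 2 and 53.35 RPKM in Vismodegib replicate 3. In the other libraries it was 24.18 to 48.96 RPKM. Most of it came from Gpa33, Anpep and Rbp2, which every library expressed. Without these 3, left out after their values were seen, it was 5.36 and 17.25 RPKM, and 1.79 to 4.58 RPKM in the other libraries.

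For the number of genes and of lists, the 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. In 10 of the 10 splits the count of genes was as large as the real 0, the highest other being 0, which had to be so since no count is under 0, and in 10 of the 10 the count of lists was as large as the real 9, the highest other being 16. Unadjusted p under 0.05 were found by limma for 266 genes in the real split and for 77 to 1432 in the other splits. The highest count came from DMSO replicate 1 with Vismodegib replicates 1 and 3 against the rest. The treatment was thus not the split with the most such genes, and what sets the libraries apart was not tested. The first principal component, 46.1% of the variance, set DMSO replicate 1 (-43.6) apart from DMSO replicate 2 (61.0).

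Of the tests in the paragraphs that follow, those of a single DMSO library and of neighbouring tissue were chosen only after the result was seen, and so were the margins for sampling error around the bounds for the shares of marker genes. The higher mitochondrially encoded transcripts lean in part on DMSO replicate 2, without which the list's median falls to 0.479 of its value (0.44 against 0.91). This library had the list's lowest per-library median, -1.349, so leaving it out would lower the difference whatever the cause. The fall shows how much of the difference rests on that library, not why. Leaving out Vismodegib replicate 1 also lowered the median. With each library's trend on GC content and length removed, the median was 0.573 of its value (0.52), between the bounds of 0.5 and 0.75 set for and against such a bias, so the bias remains open. An effect of the treatment was not tested separately and also remains open.

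The higher fat, muscle, fibroblast and matrix genes stayed when trends on GC content and length were removed, the median over their 74 members keeping 0.926 of its value (0.56 against 0.60), which argues against that bias as the whole cause. A candidate explanation is that the dissected tumours held varying amounts of neighbouring fat pad and body wall. Within groups, muscle and fat genes deviated together with mean correlations of 0.829 and 0.311, against 95th percentiles of 0.26 and 0.308 for 1000 random lists matched on expression, the lower of the 2 percentiles reached being 95.1. Both lists lay above the bound of 95 set for neighbouring tissue, but the fat list by less than the sampling error of 1000 random lists. The test decides nothing in any case, since G2/M genes, which mark no neighbouring tissue, reached 0.824 against 0.204. Neighbouring tissue and an effect of the treatment on the stroma therefore cannot be told apart here.

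Vismodegib replicate 3 held intestinal and cornified-layer transcripts above their levels in the other libraries, found by looking at the genes that set this library apart. Apoa4 and Fabp1, made by small intestine, were at 23.6 and 8.92 RPKM there, at 5.52 and 1.87 RPKM in DMSO replicate 2 and at most 0.31 and 0.22 RPKM in the other 4 libraries, and the cornified-layer genes Calm4 and Krtdap were at 95.02 and 27.2 RPKM against at most 2.21 and 1.97 RPKM elsewhere. Of 25 small intestine genes detected (at least 0.1 RPKM in any library, a level set after some marker values were seen) and not used to find the pattern, 18 were highest in this library, a share of 0.72 between the bounds of 0.8 and 0.4, so that intestinal RNA remains a candidate source; 13 of the 25 also had a mean of at least 0.1 RPKM over the other 5 libraries. Liver is argued against, since 2 of 10 detected liver genes were highest there, a share of 0.2 (exact 95% interval 0.025 to 0.556), and Alb was at 0.04 RPKM. For skin, 9 of 12 detected keratinocyte differentiation genes were highest there. Of the 12, 6 also had a mean of at least 0.1 RPKM over the other 5 libraries. Of these 6, Krt10, Asprv1 and Sbsn were highest there and Ivl, Tgm1 and Krt80 were not. Genes that reached 0.1 RPKM only in this library had to be highest there, in the intestinal count too. Of detected hair follicle and melanocyte genes, 1 of 4 was highest there, a share of 0.25 (0.006 to 0.806). This is too few to decide, though the bound without the margin would have counted against skin with hair follicles. Carry-over between samples, reads assigned to the wrong library and a biological explanation were not tested.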
